A study of Mus musculus with 6 samples.

How the data were processed

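Poly-A RNA of MLL-ENL/NrasG12D leukemia cells was made into stranded mRNA libraries, per the labels' protocols, with 3 libraries from cells treated with DMSO and 3 from cells treated with 5 µM EPZ015666. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.0 and DESeq 1.16.0 and the genome build mm10, without saying which step each served. The annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Genes that overlap or have near-identical copies (histones, ribosomal proteins, Lyz2, MHC genes, chemokines, Bcl2a1 genes) are therefore less certain than others.

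The authors deposited 1 table with a value for each of 11644 genes in each of the 6 libraries. Its values are a normalized signal: read counts per gene that the authors had divided by a size factor for each library. This was worked out from the values. In every library 100% of the values were whole multiples of 1 step, within a tolerance of 1e-06, so whole reads were recovered, and median-of-ratios size factors recomputed from those reads equalled the inverse of the steps. They ranged from 0.715 (inhibitor library 2) to 1.24 (DMSO library 2). The values are called normalized counts here. Each gene in the table has at least 10 reads in its highest library, and no further filter was set. Recovered reads per library ran from 11335948 to 19197912. This depth limits precision for low genes, for which a rise can rest on few reads in DMSO.

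No pair of libraries in a group agreed within sampling noise: the chi-square per degree of freedom over genes was 9.43 to 20.7 within groups, so no library was treated as a duplicate of another. This does not show that the libraries came from separate cultures. Inhibitor and DMSO libraries were compared with limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), over all genes, without a block for the replicate number. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, and the residual degrees of freedom were 4. The design had named edgeR's quasi-likelihood test for raw counts and limma-trend for normalized values; the table held the latter. On the recovered reads, edgeR 4.0.16 (TMM factors) called 5291 genes and is given as an alternative. Means are of normalized counts with the SD over 3 libraries, folds between groups are ratios of these means, and log2 fold changes carry the limma standard error on the log2(value + 1) scale, which understates changes of low genes.

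The groups, the tests, 35 gene lists and the rule for named genes were set before the data were examined. The lists cover p53 targets, cell cycle, DNA repair, MYC and ribosome genes, MLL-fusion targets, the PRMT5 complex and related enzymes, splicing, signalling, metabolism, myeloid maturation and other blood or stromal cell types. Lists with at least 5 measured members were tested with camera (limma), with a preset correlation between genes of 0.01, and adjusted over the 32 lists. The design had written log2 CPM for this test; the scale of the limma fit was used because the table is normalized, and log2 CPM was run as an alternative. Camera with an estimated correlation and the rotation test fry were run beside it. By fry, which does not compare a list with other genes, 17 lists passed for direction and 32 for change in either direction.

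Genes were named by this rule. Prmt5, Wdr77, Cdkn1a and Mdm4 were named whatever their values. The 10 largest rises and 10 largest falls were taken among genes past the threshold, with a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and an established gene name. From each called list, and from the MLL-fusion, methylosome and p53 lists whatever their result, up to 4 members with the smallest adjusted p were named. Other list members given as examples were chosen after their values were seen. Some list members are counted but not reported here by name. Coordinates, strand, transcript length, GC content and intron number come from GENCODE mouse release 21 on the mm10 assembly, to which 11539 genes (99.1%) were matched by symbol or synonym.

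Alternatives were other size factors (DESeq2, upper quartile), DESeq2 1.42.0, limma-voom, edgeR without a filter or with at least 5 CPM in 3 libraries, pseudocounts of 0.5 and 5, a replicate block, a 2-fold minimum, and leaving out each library in turn. With a library left out, fewer genes were called in all (4145 to 5346 in place of 5418). A lower count in a list is then not by itself particular to that list. Thinning to equal depth, log2 CPM with TMM factors, removal of GC and length trends, and a minimum mean of 100 normalized counts were added after the data had been seen. On simulated counts for 11644 genes with these means and depths, limma-trend recovered 49.3% of genes changed by 0.5 on the log2 scale. It recovered 80.6% of those changed by 1 and 92.4% of those changed by 2, with 12 false calls. Far fewer genes were changed in the simulation than were called in the data (5418). The recovery rates and the number of false calls therefore do not carry over to the data. Camera called the 1 list that had been shifted, that of G2/M and mitosis genes. Genes were simulated independently of each other, so camera was not tested where members of a list vary together. In the data the estimated correlation of that list was 0.45, against the preset 0.01. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.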

Results

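The transcriptome of MLL-ENL/NrasG12D cells, a mouse myeloid leukemia line, was compared after 72 h of culture with the PRMT5 inhibitor EPZ015666 or with its solvent, DMSO. These cells carry a fusion of the histone methyltransferase MLL with ENL, a partner from the transcription elongation machinery, together with an activated form of the small GTPase Nras. PRMT5 is the main enzyme that places symmetric dimethyl groups on arginine residues of histones, Sm proteins and other substrates, and EPZ015666 is a small molecule that inhibits its catalytic activity. The inhibitor was used at 5 µM and treatment was repeated on day 2. The comparison asks which transcripts differ in MLL-rearranged leukemia cells when PRMT5 is inhibited. Polyadenylated RNA was sequenced from 3 DMSO libraries and 3 inhibitor libraries, called independent replicates in the series text, which does not say what was repeated. The p-values of single genes below therefore set the group difference against the spread within the groups of these 6 libraries, as moderated over genes by limma. Those of gene lists by camera compare a list with the other genes at the preset correlation of 0.01. They do not measure replication between libraries alone.

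The DMSO libraries held 19197912, 19119995 and 15505127 reads assigned to genes, and the inhibitor libraries 15551525, 11335948 and 14525098. The 10 most abundant genes took between 5.13% and 6.21% of the reads of a library. Over 11644 genes, Pearson correlations of log2 values (across genes, which are not independent replicates) were 0.987 to 0.992 within a group and 0.951 to 0.962 between groups. The first principal component held 74.5% of the variance and separated the inhibitor from the DMSO libraries. The next component, with 9.0%, set DMSO library 2 (score -29.2) apart from DMSO libraries 1 and 3 (13.5 and 12.3). DMSO library 2 held more transcripts of stress genes than the other two: Trib3 stood at 1376 normalized counts against 126 and 218, Ddit3 at 1378 against 171 and 237, and Nupr1 at 249 against 37.5 and 44.2. Mpo, which encodes myeloperoxidase, stood at 371 in that library against 1438 and 731.

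Prmt5 itself (chromosome 14, 54507187 to 54517525, minus strand) was close in both groups, with 2784 ± 366 normalized counts in DMSO and 2508 ± 373 with the inhibitor (SD, n = 3 per group). Its log2 fold change of -0.15 ± 0.12 (SE) did not pass the test (limma adjusted p = 0.316). The compound acts on the enzyme, so the transcript level does not check the inhibition. Coprs, a cofactor that ties PRMT5 to histones, rose 2.46-fold, from 118 ± 31.0 to 290 ± 9.80 (limma adjusted p = 9.36e-05). Wdr77, the obligate WD-repeat partner of PRMT5, fell from 2138 ± 129 to 1852 ± 44.6, a log2 change of -0.21 at the edge of the test (limma adjusted p = 0.0490). Of the 5 methylosome genes, Coprs rose, Wdr77 fell and Riok1, Clns1a and Prmt5 did not pass; adjusted over the list alone, Coprs passed and Wdr77 did not. The list as a whole had a median log2 fold change of -0.07, a mean of 0.22 and a test direction upward, and was not called (camera adjusted p = 0.800). The call on Wdr77 was lost without DMSO library 1 (limma adjusted p = 0.195) or 3 (0.0930), and without inhibitor library 1 (0.0539), 2 (0.123) or 3 (0.0925).

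Among 8 other protein arginine methyltransferase genes and relatives, Prmt2 rose (57.7 to 146 normalized counts) and so did Prmt6 (521 to 657), while Carm1 (864 to 568), Prmt3 (1377 to 923), Prmt7 (1306 to 1012) and Prmt10 (476 to 399) fell. Prmt1, the main enzyme of asymmetric dimethylation, had 1846 and 1866. The counts of 2 risen and 4 fallen genes held when adjusted over the list alone, and the list was not called (camera adjusted p = 0.608). Of the 2 rises, 1 was left without DMSO library 3 or without inhibitor library 2.

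Inhibitor treatment changed 5418 of 11644 genes at an adjusted p under 0.05 (limma), or 46.5%: 2753 were higher and 2665 lower than in DMSO. With a change of at least 2-fold as well, 834 genes were higher and 354 lower. Fold changes on the log2 scale are of the normalized count + 1 and understate the change of low genes. Of 32 gene lists tested together, 12 were called by camera, 7 upward and 5 downward, and the list of p53 targets alone stayed past the threshold with an estimated correlation. Clec4n, the pattern-recognition lectin dectin-2, rose 34.7-fold, to 452 ± 101 normalized counts, and Tnip3, an inhibitor of NF-kB signalling, from 32.3 ± 14.1 to 1068 ± 59.1 (SD, n = 3 per group). The scavenger receptors Stab1 and Msr1 rose 24.9-fold and 20.1-fold, the chemokines Ccl2 and Ccl7 24.7-fold and 29.5-fold, and the gelatinase Mmp9 30.8-fold. Sulf2, an extracellular sulfatase, rose 33.0-fold, to 196 ± 1.92, and Fam20c, a kinase of secreted proteins, and Acsbg1, an acyl-CoA synthetase, rose 23.8-fold and 22.0-fold. The limma adjusted p of these 10 genes lay between 2.10e-08 and 5.70e-06. Several rest on few reads in DMSO: Ccl7 had 10 reads over the 3 DMSO libraries, Sulf2 21 and Mmp9 24. In DMSO libraries 1 and 3 Fam20c stood at 8.15 and 10.8 and Acsbg1 at 2.45 and 5.89, against 29.1 and 12.9 in library 2.

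Prss57 (chromosome 10, 79781474 to 79790961, minus strand), which encodes a serine protease of neutrophil granules, fell most of all genes on the log2 scale, from 145 ± 22.1 to 4.79 ± 1.85 normalized counts (SD, n = 3 per group; log2 fold change -4.70 ± 0.29 SE, limma adjusted p = 3.64e-07). Other large falls included metabolic genes: Pycr1, an enzyme of proline synthesis, fell from 304 ± 22.6 to 50.7 ± 14.1, Csad, of taurine synthesis, from 218 ± 30.2 to 45.9 ± 5.91, and Macrod1, an ADP-ribose hydrolase, 7.08-fold, to 17.3 ± 5.70. The receptors Adgrl1 and S1pr3 fell 5.47-fold and 5.07-fold, the nuclear membrane gene Nrm 5.26-fold, Gcsam 4.94-fold and Itih5 4.35-fold. Slc6a9, a glycine transporter, fell from 200 ± 122 to 40.4 ± 9.71 (limma adjusted p = 2.89e-04); its DMSO values were 121 and 137 in libraries 1 and 3 and 341 in library 2.

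**Figure D1:**
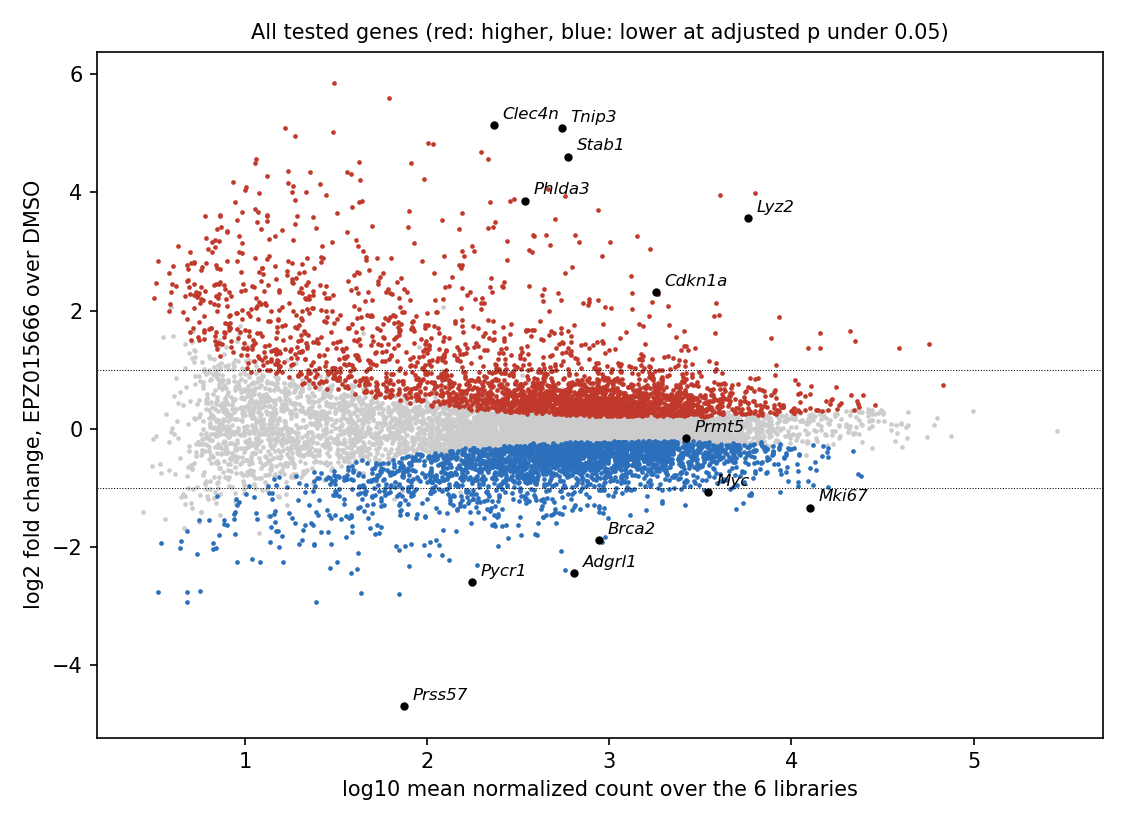
Log2 fold change (EPZ015666 over DMSO, log2 of normalized count + 1) of each of 11644 genes against the log10 of its mean normalized count over the 6 libraries. Red points are the 2753 higher and blue points the 2665 lower genes, dotted lines mark 2-fold, and 13 genes are named; Clec4n and Tnip3 lie above 5 on the log2 axis, while Prss57 lies at -4.70.

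Most genes listed as p53 targets rose. The binding and activity of p53 were not measured here. Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand), the p21 inhibitor of cyclin-dependent kinases, rose 4.92-fold, from 610 ± 143 to 2999 ± 201 normalized counts (SD, n = 3 per group; log2 fold change 2.32 ± 0.13 SE, limma adjusted p = 2.30e-07). Phlda3, a repressor of AKT signalling, rose 14.8-fold (to 646 ± 55.4), Trp53inp1, a stress-induced cofactor of p53, 4.86-fold (630 ± 32.3 to 3060 ± 228) and Fam212b 11.6-fold (37.3 ± 4.81 to 434 ± 43.6). Of 43 measured p53 targets, 35 rose, 1 fell (Arap2) and 7 did not pass; adjusted over the list alone, 37 rose and 1 fell. The rises included the p53 ubiquitin ligase Mdm2 (1595 to 5962), the cyclin Ccng1 (3659 to 13498), the pro-apoptotic Bax (1442 to 3816) and Bbc3 (681 to 950), the death receptor Fas (2.81 ± 3.31 to 26.5 ± 7.29, with a DMSO SD above the mean) and Zmat3 (186 to 745). The list's median log2 fold change was 1.21 (camera adjusted p = 2.21e-16), and it stayed past the threshold with an estimated correlation (adjusted p = 0.0162). Mdm4, the p53 inhibitor whose splicing depends on PRMT5 in other cells, had 2705 ± 475 and 2541 ± 335 (limma adjusted p = 0.612), at the level of the whole gene; its exons were not analysed here.

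**Figure D2:**
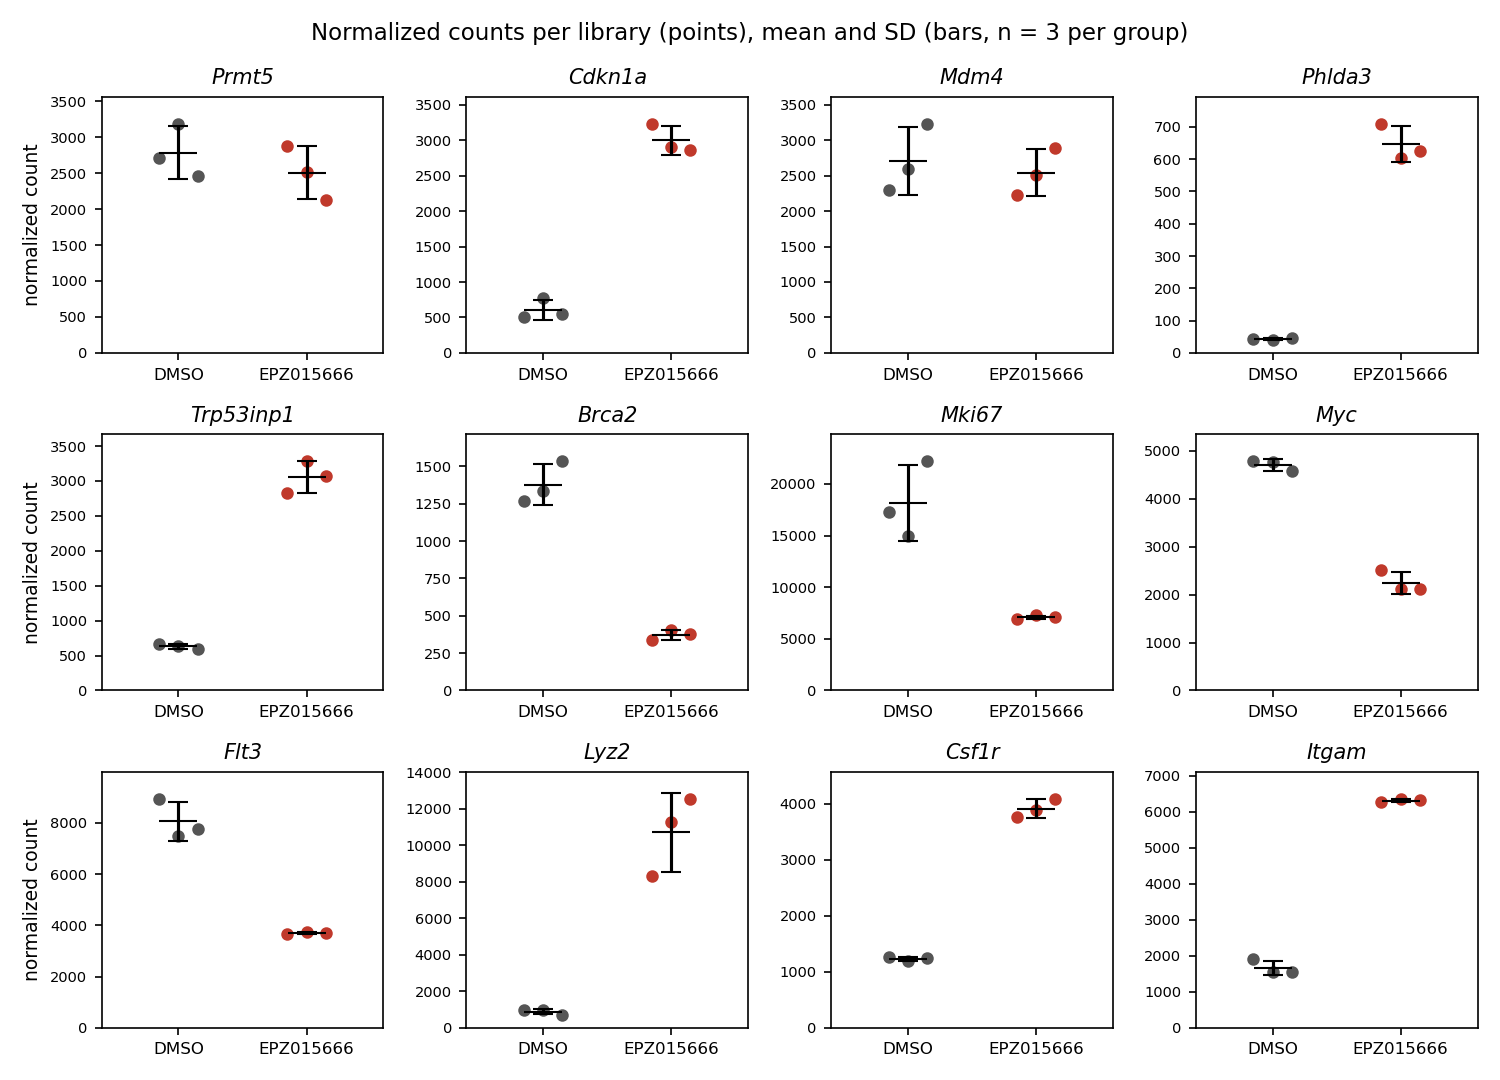
Normalized counts of 12 genes in each of the 3 DMSO (grey) and 3 EPZ015666 (red) libraries, with the group mean and SD as black bars and every vertical axis starting at 0. The groups overlap for Prmt5 and Mdm4; Cdkn1a, Phlda3, Trp53inp1, Lyz2, Csf1r and Itgam lie higher and Brca2, Mki67, Myc and Flt3 lower in every inhibitor library than in any DMSO library.

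Among the 7 cyclin-dependent kinase inhibitors, Cdkn1a, Cdkn2b (11.3 to 80.6) and Cdkn2a (239 to 396) rose and Cdkn2c fell (1759 to 1461), also when adjusted over the list alone (3 and 1). The list was not called (camera adjusted p = 0.0718), but passed without DMSO library 2 (adjusted p = 0.0358), and the fall of Cdkn2c was lost without DMSO library 1 or 3 or inhibitor library 2 or 3. In the BCL2 family and apoptosis list of 27 genes, 11 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.332). The anti-apoptotic Bcl2 fell from 10647 ± 627 to 6566 ± 479, whereas Mcl1 (3286 to 5241) and Bcl2l1 (334 to 817), which also protect from apoptosis, rose. Rises in that list numbered 6 without DMSO library 1, without DMSO library 3 or without inhibitor library 2.

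Genes of cell division were lower with the inhibitor. Mki67, the proliferation marker Ki-67, fell 2.55-fold, from 18128 ± 3695 to 7096 ± 159 normalized counts, Cdc25b, a phosphatase that starts mitosis, from 733 ± 44.8 to 355 ± 28.6, and the condensin subunit Ncapd2 from 6386 ± 706 to 3225 ± 233 (SD, n = 3 per group). Kif15, a spindle kinesin, fell 1.86-fold. Of 62 G2/M and mitosis genes, 45 fell and 17 did not pass, also when adjusted over the list alone, with a median log2 fold change of -0.42 (camera adjusted p = 2.93e-10; adjusted p = 0.617 with an estimated correlation). Aurka (1509 and 1469), Bub1 (2197 and 2339) and Birc5 (1400 and 1344) were among the latter.

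Among 53 S-phase and DNA replication genes, 30 fell and 3 rose, also when adjusted over the list alone. The smallest adjusted p were those of Rnaseh2a, a subunit of the nuclease that removes ribonucleotides from DNA (1074 ± 101 to 439 ± 30.0), the DNA polymerase subunits Pold1 (2717 ± 234 to 1169 ± 119) and Pole (3467 ± 432 to 1875 ± 91.6), and thymidine kinase, Tk1 (1518 ± 96.0 to 805 ± 20.0). Ccne2 (1139 to 1822), Tyms (1422 to 1697) and Orc6 (934 to 1128) rose, and Pcna (7193 and 7955) did not pass. The list's median log2 fold change was -0.31 (camera adjusted p = 5.04e-06; adjusted p = 0.617 with an estimated correlation). Without inhibitor library 2, 20 of its genes fell in place of 30 and 1 rose in place of 3. Over all genes, 2067 fell without that library in place of 2665, so part of this loss is general. DMSO library 2 lay below the other DMSO libraries for this list and for the G2/M list, by median log2 differences of -0.14 and -0.13, and DMSO library 1 lay 0.15 and 0.13 above the others.

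Replication-dependent histone transcripts fell in 17 of 23 cases and did not pass in 6; adjusted over the list alone, 19 fell. The linker histone genes Hist1h1e (14406 ± 3355 to 7271 ± 496) and Hist1h1b (11060 ± 763 to 6469 ± 356), Hist1h4d (14260 ± 2714 to 7587 ± 734) and Hist1h2ag (1319 ± 142 to 797 ± 44.3) had the smallest adjusted p. The list's median log2 fold change was -0.62 (camera adjusted p = 1.22e-06; adjusted p = 0.617 with an estimated correlation). DMSO library 2 lay higher than the other DMSO libraries for these genes, by a median of 0.46 on the log2 scale, and without it 16 fell, with a median of -0.45. DMSO library 3 lay below the others, by a median log2 difference of -0.32, and 13 fell without inhibitor library 2. These transcripts mostly lack a poly-A tail and come from near-identical gene copies, so poly-A selection and shared reads make single values uncertain.

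Homologous recombination and Fanconi genes were also lower. Brca2 (chromosome 5, 150522630 to 150570329, plus strand), a central gene of homologous recombination, fell 3.71-fold, from 1379 ± 138 to 372 ± 34.3 normalized counts (SD, n = 3 per group; log2 fold change -1.89 ± 0.10 SE, limma adjusted p = 1.38e-07). The damage-response kinase Atr fell 1.96-fold (2090 ± 141 to 1068 ± 82.3), Rad50, of the complex that senses double-strand breaks, 1.75-fold (2796 ± 92.5 to 1597 ± 183), and Rmi2 1.89-fold. Of 46 genes, 27 fell and 19 did not pass, also when adjusted over the list alone; Fancc (362 to 187) and Brca1 (1993 to 1605) were among the falls. For the list the median log2 fold change was -0.35 (camera adjusted p = 9.33e-08; adjusted p = 0.469 with an estimated correlation). For these genes DMSO library 2 lay below the other DMSO libraries, by a median log2 difference of -0.13.

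Myc (chromosome 15, 61985391 to 61990374, plus strand), the transcription factor, fell 2.10-fold, from 4707 ± 116 to 2246 ± 224 normalized counts (SD, n = 3 per group; limma adjusted p = 3.06e-06). With it fell Nop56 (7174 ± 328 to 3813 ± 376) and Dkc1 (3926 ± 153 to 2672 ± 256), both of nucleolar ribonucleoprotein particles, and Cad (4347 ± 503 to 2590 ± 307), of pyrimidine synthesis. Of 40 MYC and ribosome biogenesis genes, 19 fell, 2 rose (Polr1c and Nip7) and 19 did not pass, with the same counts adjusted over the list alone; the nucleolar protein genes Ncl and Fbl fell, and Npm1 (26138 and 29066) did not pass. The median log2 fold change was -0.24 (camera adjusted p = 0.00286; adjusted p = 0.709 with an estimated correlation). Without DMSO library 1, 12 fell, and 1 rose without DMSO library 1 or 3 or without inhibitor library 2.

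Ribosomal protein transcripts leaned the other way, by a small amount. Of 51 genes, 6 rose, among them Rpl27 (9384 ± 433 to 12892 ± 1288), Rpl38 (7273 ± 294 to 9794 ± 1008), Rps21 and Rpl24, and 45 did not pass; adjusted over the list alone, 2 rose. The list's median log2 fold change was 0.21 (camera adjusted p = 0.0146; adjusted p = 0.915 with an estimated correlation). The call was lost without DMSO library 3 (adjusted p = 0.123), without inhibitor library 3 (0.0787), and after removal of GC and length trends (0.386). The number of risen genes was 2 without DMSO library 3 or inhibitor library 2, 3 without inhibitor library 3 (with 1 fallen gene) and 23 without inhibitor library 1; Rps21 and Rpl24 lost their calls without DMSO library 3 or inhibitor library 2 or 3. Ribosomal protein genes have many processed copies in the genome, and reads shared with them add uncertainty to each value.

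Myeloid maturation genes were higher with the inhibitor. Lyz2 (chromosome 10, 117277331 to 117282321, minus strand), lysozyme of monocytes and neutrophils, rose 11.9-fold, from 897 ± 156 to 10702 ± 2163 normalized counts (SD, n = 3 per group; log2 fold change 3.57 ± 0.15 SE, limma adjusted p = 2.59e-08); reads of its close copy Lyz1 may be counted with it. Itgam, the integrin CD11b, rose 3.79-fold (1667 ± 203 to 6314 ± 44.0), Anxa1, an anti-inflammatory annexin, 4.91-fold (448 ± 31.7 to 2202 ± 210), and Mmp9 as given above. Of 30 listed neutrophil maturation genes, 16 were measured, and 9 of these had a mean of at least 100 normalized counts in DMSO. Among the 16, 13 rose and 3 did not pass, also when adjusted over the list alone. The genes that were not measured cannot be counted either way. Each gene in the table reaches at least 10 reads in its highest library, so a low gene could be present only because it rose. Cybb, the oxidase subunit, went from 694 to 2593, and the low-abundance S100a8 (5.54 to 22.0) and S100a9 (7.71 to 21.9) rose as well. Over this list the median log2 fold change was 1.67 (camera adjusted p = 8.82e-07; adjusted p = 0.122 with an estimated correlation). Without inhibitor library 3, 1 gene of the list fell.

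Csf1r, the receptor for the macrophage growth factor M-CSF, rose 3.17-fold (1235 ± 33.6 to 3912 ± 165), Lgals3, galectin-3, 8.73-fold (140 ± 42.9 to 1225 ± 71.3), the Fc receptor Fcgr3 2.67-fold and the endotoxin co-receptor Cd14 5.43-fold (80.0 ± 13.4 to 435 ± 86.0). Of 28 monocyte and macrophage genes, 21 rose and 2 fell, also when adjusted over the list alone; those that fell were Irf8 (5469 to 3032), a transcription factor of the monocyte lineage, and Mrc1 (18.1 to 8.71), the macrophage mannose receptor. The median log2 fold change was 1.31 (camera adjusted p = 9.33e-08; adjusted p = 0.173 with an estimated correlation). In DMSO, 17 of these 28 genes already had a mean of at least 100 normalized counts, and 3 of them also stand in another list. The number of fallen genes was 1 without DMSO library 2 or 3, or without inhibitor library 2 or 3.

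Primary granule and early granulocyte genes went both ways. Of 12 genes, 7 fell and 4 rose, also when adjusted over the list alone: Prss57, Prtn3 (1496 to 403), Mpo (847 ± 543 to 342 ± 59.1), Ctsg, Serpinb1a, Clec12a and the transcription factor Cebpa (1269 to 873) fell, while Ms4a3, Igsf6 (268 to 815), Srgn and Calr rose. The list was not called (median -0.29, camera adjusted p = 0.360). DMSO library 2 lay below the other DMSO libraries for this list, by a median log2 difference of -0.26, and DMSO library 1 lay 0.35 above the others. The number that fell was 4 without DMSO library 1 or without inhibitor library 3.

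Several transcripts of MHC class II genes were higher with the inhibitor. Cd74, the invariant chain, went from 378 ± 124 to 1527 ± 143 normalized counts, H2-Aa rose 5.18-fold, and Cd80, a co-stimulatory ligand, went from 36.9 ± 9.26 to 394 ± 63.4 (SD, n = 3 per group). Ciita, the master regulator of class II genes, rose from 6.92 ± 5.92 to 33.9 ± 3.95. Of 19 MHC class II and dendritic cell genes, 11 rose and 2 fell (Flt3 and Siglech, both of dendritic cell progenitors or plasmacytoid cells); adjusted over the list alone, 12 rose and 2 fell. The median log2 fold change was 0.64 (camera adjusted p = 0.00194; adjusted p = 0.617 with an estimated correlation). For this list DMSO library 2 lay 0.28 above the other DMSO libraries on the log2 scale, and DMSO library 1 lay below the others by a median log2 difference of -0.29.

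Several transcripts of lysosomal enzymes rose: Ctsb, cathepsin B, from 7126 ± 1475 to 21731 ± 1421, Ctsd, cathepsin D, from 10265 ± 2249 to 31767 ± 2215, the sialidase Neu1 2.81-fold and the galactosidase Gla 2.17-fold. Of 38 lysosome and autophagy genes, 21 rose and 2 fell (Ctsa and Glb1); adjusted over the list alone, 22 rose and 2 fell. Their median log2 fold change was 0.34 (camera adjusted p = 2.12e-05; adjusted p = 0.617 with an estimated correlation). Over this list DMSO library 2 lay 0.16 above the other DMSO libraries on the log2 scale, in the direction of the inhibitor libraries. Ctsb, Ctsd and Ctss stand in the macrophage list as well.

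NF-kB and inflammatory genes were higher with the inhibitor: Ccl2 rose from 16.9 ± 3.79 to 417 ± 43.3, Ccl6 5.42-fold, Ccl9 from 3940 ± 651 to 11418 ± 1314, and the immediate early gene Ier3 3.25-fold (SD, n = 3 per group). Of 25 genes, 19 rose, 1 fell (Nfkb1) and 5 did not pass; adjusted over the list alone, 21 rose and 1 fell. The median log2 fold change was 1.19 (camera adjusted p = 1.22e-06; adjusted p = 0.617 with an estimated correlation). DMSO library 2 lay above the other DMSO libraries by a median of 0.83 on the log2 scale for these genes, in the direction of the inhibitor libraries. Without it 24 genes rose, with a median of 1.53. DMSO library 1 lay below the others, by a median log2 difference of -0.49, and 13 genes rose without it.

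**Figure D3:**
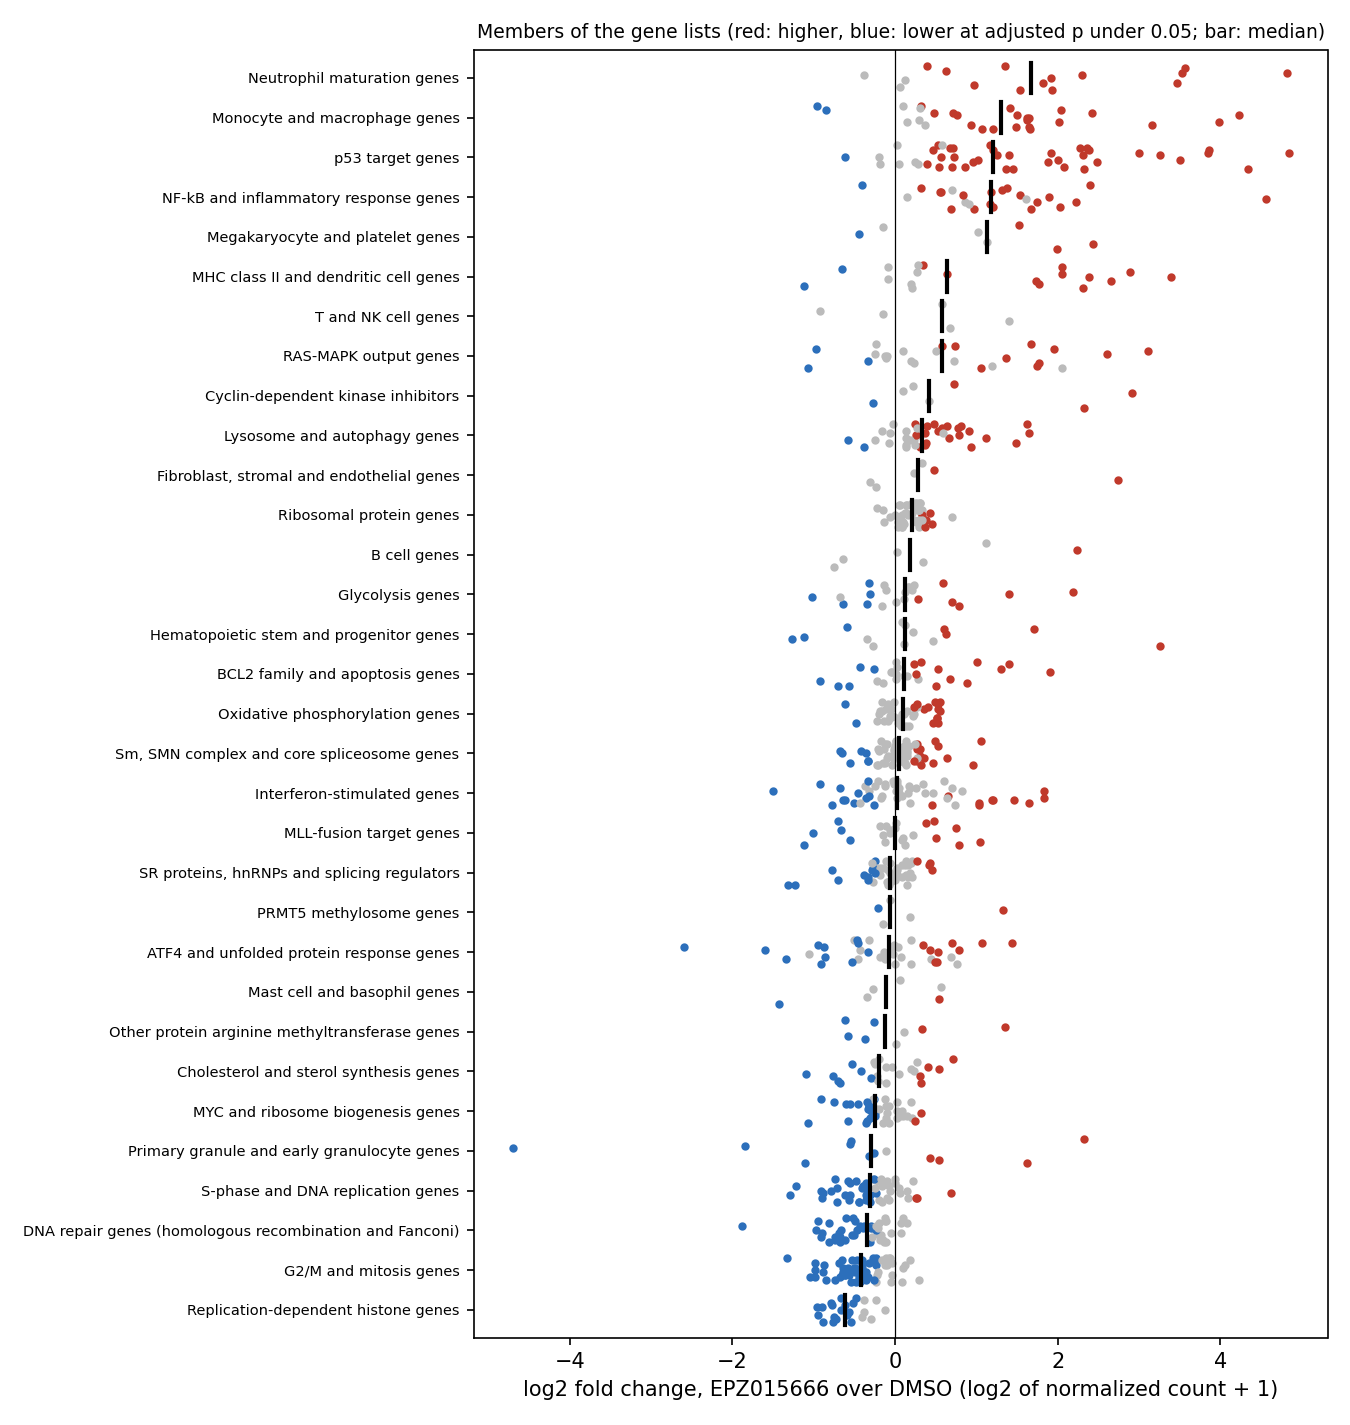
Log2 fold change (EPZ015666 over DMSO, log2 of normalized count + 1) of the members of the 32 lists with at least 5 measured genes, sorted by median. Points are genes, red where higher, blue where lower and grey where not past the test, and the black bar is the list's median; neutrophil maturation genes have the highest median (1.67) and replication-dependent histone genes the lowest (-0.62).

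Targets of MLL fusions did not move as a group. Flt3 (chromosome 5, 147330741 to 147400489, minus strand), a receptor kinase of leukemic progenitors, fell 2.18-fold, from 8060 ± 763 to 3693 ± 28.5 normalized counts (SD, n = 3 per group; limma adjusted p = 2.55e-06). The transcription factor Runx1 fell 2.02-fold (1448 ± 202 to 717 ± 33.3), and Bcl2 1.62-fold, Cdk9 1.46-fold and Hmgb3 (1015 to 639) fell as well. Hoxa5 (159 to 274), Hoxa6 (54.9 to 93.1), Hoxa7 (405 to 571), Hoxa9 (2608 to 3617) and Zeb2 (2776 to 3605) were among those that rose, while Meis1 (1224 and 1301), Myb (6968 and 6282) and Mef2c (7733 and 7462) did not pass. The counts of 6 risen and 5 fallen among 23 genes were the same adjusted over the list alone, and the list was not called (median -0.01, camera adjusted p = 0.800).

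Of 14 stem and progenitor genes, 4 rose (Procr, Ly6a, Tal1 and Cd34, the last from 8846 to 13430) and 3 fell (Flt3, Msi2 and Egfl7), also when adjusted over the list alone, without a call for the list (camera adjusted p = 0.800). Kit had 831 and 687. Without DMSO library 2, 5 of these genes fell.

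Genes of the splicing machinery, which contains the Sm substrates of PRMT5, changed in both directions. In both lists that follow, the share of genes called was below the 46.5% over all genes. Of 61 Sm, SMN complex and core spliceosome genes, 14 rose and 7 fell (11 and 7 adjusted over the list alone), without a call (camera adjusted p = 0.532); Prpf3 went from 631 to 1315 and Bud31 from 1114 to 2173, while Dhx38 went from 2060 to 1289 and Prpf19 from 3846 to 2476. Of 49 SR protein, hnRNP and splicing regulator genes, 4 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.332), with Taf15 (613 to 262), Mbnl3 (915 to 367) and Hnrnpr (2948 to 1725) among the falls. The counts moved when a library was left out: the core spliceosome rises numbered 8 without DMSO library 2 or 3 and 6 without inhibitor library 2, its falls 3 without DMSO library 1 or inhibitor library 2, and the regulator falls 7 without DMSO library 1, 6 without DMSO library 3 and 5 without inhibitor library 2, with 2 regulator rises without DMSO library 1. Splicing itself was not measured by gene-level values.

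RAS-MAPK output genes, relevant to cells with an activated Nras, numbered 25, of which 10 rose and 3 fell, also when adjusted over the list alone. Ccnd1, cyclin D1 (8001 to 20596), Epha2 (97.5 to 845) and Fos (203 ± 129 to 573 ± 13.6) rose, while Myc and Etv4 fell and Dusp6 (3386 and 3869) did not pass. The list was not called (camera adjusted p = 0.0718), but was called upward without DMSO library 2 (adjusted p = 9.96e-04), which lay 0.36 above the other DMSO libraries on the log2 scale for these genes.

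Metabolic and stress lists were not called. Of 42 oxidative phosphorylation genes, 13 rose and 2 fell (camera adjusted p = 0.184); without DMSO library 1 the list was called upward (adjusted p = 0.0386). Of 22 glycolysis genes, 6 rose, Pkm (13356 to 21819) and Pgam1 (10106 to 15138) among them, and 5 fell (camera adjusted p = 0.800); 3 fell without inhibitor library 2 or 3. Of 25 cholesterol synthesis genes, 5 rose and 7 fell (camera adjusted p = 0.360); 13 fell without DMSO library 2, and 3 rose without inhibitor library 2. Of 40 ATF4 and unfolded protein response genes, 9 rose and 11 fell (camera adjusted p = 0.638); DMSO library 2 lay 0.48 above the other DMSO libraries on the log2 scale for this list, and 14 rose without it. Of 53 interferon-stimulated genes, 10 rose and 12 fell, with a median of 0.02, a mean of 0.16 and a test direction downward (camera adjusted p = 0.822); DMSO library 2 lay 0.29 above the other DMSO libraries on the log2 scale, and 16 rose without it. In these 5 lists the counts adjusted over the list alone were the same.

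Markers of other cell types were few and mostly low, and their lists were not called; counts adjusted over the list alone were the same. Of 7 megakaryocyte and platelet genes, Selp, Itga2b and Vwf (120 to 347) rose and Nfe2 fell (camera adjusted p = 0.223); DMSO library 1 lay below the other DMSO libraries for this list, by a median log2 difference of -0.64. Of 6 mast cell and basophil genes, Srgn rose and Mcpt8 fell (camera adjusted p = 0.822), with 3 falls without DMSO library 2. Of 6 B cell genes, Blnk rose (camera adjusted p = 0.638), and of 6 fibroblast, stromal and endothelial genes, Vim and Acta2 rose (camera adjusted p = 0.357); without inhibitor library 3, 1 gene fell in each of the B cell and stromal lists. Of 5 T and NK cell genes, 0 were called by limma, edgeR, DESeq2 or limma-voom, and 3 had an unadjusted limma p under 0.05 (camera adjusted p = 0.800); without DMSO library 2, 2 rose, and without inhibitor library 1, 1 rose. Too few genes were measured for a test of the erythroid list, in which Tfrc fell and Rhd did not pass, and of the eosinophil list, in which Siglecf fell (96.2 to 58.6); the mitochondrially encoded list was not analysed here.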

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

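Thinning, log2 CPM with TMM factors, removal of GC and length trends and the minimum mean of 100 were chosen after seeing the data; the other settings were planned. The number of changed genes (5418) lay between 4479 and 5556 under the other tests, factors, pseudocounts, filters and corrections, and between 4145 (without inhibitor library 2) and 5346 (without DMSO library 2) with a library left out. No gene called in the main fit changed sign under any of the settings in which it was tested. A 2-fold minimum, which by construction keeps fewer genes, left 1188 genes, 834 higher and 354 lower. The share of called genes that were higher was 50.8%, and 47.4% to 52.6% over the other tests, scalings, corrections and left-out libraries, with a median log2 fold change of all genes between -0.02 and 0.01; with the minimum mean of 100, 2106 of 4479 were higher. Of 73 named genes, Wdr77, Rps21 and Rpl24 alone lost their call in some setting; besides the left-out libraries, Wdr77 lost it with edgeR on DESeq2 size factors (adjusted p = 0.0505), DESeq2 (0.0592) and the 5 CPM filter in limma (0.0507), and Rps21 and Rpl24 after removal of GC and length trends (0.108 and 0.141); the cause was not tested.

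The 12 called lists are less firm than the genes. With an estimated correlation 1 list passed, 1 upward (p53 targets) and 0 downward; at an unadjusted camera p under 0.05, 3 lists passed upward and 0 downward. The estimated correlations of the 11 lists that lost their call ran from 0.0196 (neutrophil maturation) to 0.705 (ribosomal proteins), against the preset 0.01. The neutrophil list lost its call (camera adjusted p = 0.122) although its estimate was near the preset. A higher correlation alone therefore does not account for every loss, and other causes were not tested. Fry called 12 lists upward in place of 7, adding cyclin-dependent kinase inhibitors, megakaryocyte, B cell, stromal, BCL2 family and RAS-MAPK genes and losing ribosomal proteins; it asks another question. Between 11 and 14 lists were called with a library left out, and 11 to 12 under the other filters and corrections.

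The series text states no pairing, so the replicate numbers were not used as pairs in the main fit. Correlations of deviations for numbers 1, 2 and 3 were 0.17, 0.05 and 0.21, and those between different numbers -0.16 to -0.003. Of 6 libraries, 6 correlated best with their own number. Deviations from a group mean cancel out over the libraries of a group, so these 6 matches are not separate observations. Pairing is at most weakly hinted at by the data and is not given by the design. With a replicate block, 5932 genes and 13 lists were called; the added list was RAS-MAPK output (adjusted p = 0.0491), and no other list or named gene changed its call. Depth limits the low genes: the shallowest library held 11335948 reads.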

Other observations

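Genes of this paragraph and the next were picked after their values were seen and were not tested as groups. Within the ATF4 and unfolded protein response list, some enzymes of amino acid metabolism fell: besides Pycr1, Aldh18a1, the step before it in proline synthesis, went from 3431 to 1825 normalized counts, Gpt2, an alanine aminotransferase, from 775 to 249, Shmt2, of mitochondrial serine and glycine metabolism, from 6585 to 3426, and Phgdh and Psat1, of serine synthesis, from 8709 to 6065 and from 5278 to 4184 (all limma adjusted p under 0.05, n = 3 per group). Atf4 itself had 6305 and 6241 and did not pass, nor did Asns, of asparagine synthesis (4016 and 3180, with 5130 in DMSO library 2 against 3412 and 3506 in the other DMSO libraries). Some genes of the endoplasmic reticulum in the same list rose: the chaperone Hspa5 from 13697 to 19228, Calr from 13865 to 18513, Manf from 1900 to 2705, Creld2 from 655 to 945, and Edem1, of the degradation of misfolded glycoproteins, from 5278 to 11149. DMSO library 2 lay 0.48 above the other DMSO libraries on the log2 scale for this list.

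Within the interferon list, some genes of MHC class I presentation fell: H2-K1 from 11454 to 7338, H2-D1 from 3880 to 2050, B2m from 17124 to 12435, the peptide transporter Tap1 from 3145 to 1971 and the immunoproteasome subunit Psmb9 from 1463 to 513. Tap2 (4125 and 4169) and Psmb8 (5833 and 5714) did not pass. Other genes of the same list rose, such as the antiviral Mx1 (102 to 268), Usp18 (208 to 436) and Oas2 (157 to 318). Class I genes are a family with similar sequences, and shared reads make H2-K1 and H2-D1 less certain.

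Of the tests that follow, the minimum mean of 100 normalized counts, thinning to equal depth, removal of GC and length trends, the comparison of repair with replication genes, and the tests of macrophage markers and of stem and progenitor genes were chosen after the result was seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 5418 genes and the highest other split 0 by limma (16 to 280 genes at an unadjusted p under 0.05), so that 1 of the 10 splits gave as many genes. Every other split put libraries of both treatments in each group, so the treatment difference entered the spread within groups. Few gene calls in those splits follow from that, and their 0 is no test of chance. For gene lists by camera, the real split called 12 and the highest other 18, that of DMSO libraries 1 and 3 and inhibitor library 1 against the rest. In all, 6 of the 10 splits, the real one included, gave at least as many lists as the real one. The mixed splits keep part of the treatment difference, so this comparison cannot tell whether the list calls arose by chance.

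At least 2-fold rises outnumbered 2-fold falls by 834 to 354, a ratio of 2.36 (95% exact binomial interval 2.08 to 2.68, which treats genes as independent). Low-count genes took part in this: 526 of the 834 rises and 161 of the 354 falls had a mean under 100 normalized counts. They do not account for all of it, since the ratio among genes with a mean of at least 100 was 1.596 (1.33 to 1.92). The lower depth of the inhibitor libraries is argued against by thinning all libraries to the shallowest, after which the ratio was 2.34 (2.06 to 2.66). An effect of the inhibitor remains as a hypothesis.

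The fall of homologous recombination and Fanconi genes was set against properties of the genes, since these have many introns (median 13.5 against 8 over all genes) and PRMT5 acts on splicing factors. After removal of GC and length trends the list was still lower (median log2 fold change -0.34, camera adjusted p = 1.27e-07), which argues against those trends as the whole cause. Before that removal the list's call was lost with an estimated correlation (adjusted p = 0.469). Of 10000 random lists matched on intron number and expression, 0 had a median as low as -0.35 (the median of the random lists was -0.06), which argues against intron number alone. The fall cannot be told apart from that of replication genes as a whole: the medians of both lists differed by -0.0346 on the log2 scale (permutation p = 0.681), and gene-level values do not separate a lower share of cycling cells from a change at repair genes. A direct effect on repair genes therefore stays an untested hypothesis.

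Monocyte, macrophage and neutrophil maturation genes rose, 34 in all. Their calls did not hinge on the unequal depth of the libraries, since 33 of these 34 stayed past the threshold after thinning. The test for resident-type macrophages mixed into the cultures depends on the markers picked. C1qb, C1qc, Mrc1 and Apoe, abundant in such cells, together rose by 102 normalized counts, a sum lowered by the fall of Mrc1. This was 0.0104 of the rise of Lyz2 (9805) and argues only against macrophages rich in these 4 transcripts. Stab1 (46.1 to 1148) and Msr1 (9.15 to 184), scavenger receptors of tissue macrophages among other cells, rose, and macrophages low in those 4 transcripts are not excluded. A shift from less to more mature cells in the culture and a change within each cell cannot be told apart, since the RNA is from bulk cultures: the stem and progenitor list went both ways (median 0.12, camera adjusted p = 0.800).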
